A study of Homo sapiens and Mus musculus with 37 samples.

How the data were processed

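Single cells were sorted into multiwell plates, and ribosome-protected fragments (footprints) were cut with micrococcal nuclease and sequenced per well, per the labels' protocols. Reads were demultiplexed with bcl2fastq 2.20.0.422, trimmed with cutadapt 2.7, aligned with STARsolo 2.7.3a and collapsed with UMI-tools 1.0.1, with further steps in R 3.6.3, per the submitters' processing notes. The builds were hg38 for the human cells and GRCm38.p6 for the mouse cells, per the same notes. The annotation release, the filter that chose the cells and the treatment of reads matching several genes are not stated there.

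The deposited gene tables hold whole-number counts of footprints per gene and cell, per the file headers. The authors' cell tables also give counts of footprints in coding and untranslated sequence, and the deposited coding share is a fraction of their sum. The deposited mitochondrial share is a percent of a cell's footprints, and how it was computed is not stated. The deposited red and green values are the fluorescence signal of each cell in the sorter, in arbitrary units. The deposited cell-cycle ordering is a score between 0 and 1 by a method that is not stated, and it was not used here. The deposited codon values of the starvation plates are a ratio per cell and codon, scaled by the authors so that cells in rich medium average about 1. The site of the ribosome to which these codon values refer is not stated in the deposited table. Of 247 columns in the authors' cell tables, 144 were not used here. No file used here gives positions within a gene, and the codon values cover only the starvation plates.

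Cells count as measurements within a plate and not as replicates. Counts were summed per plate and sorted population, with at least 10 cells per sum, over all cells the authors kept. Sums were compared with edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood F test), and a gene was called at a Benjamini-Hochberg adjusted p below 0.05 within a comparison. Where populations shared a plate, the plate was a block in the fit, because both had been sorted into the same plate and processed together. Deviations of populations on one plate from their group means had a mean correlation of 0.013 in the starvation plates, 0.0085 in the mitotic and G0 plates, 0.24 and 0.239 in the geminin and CDT1 reporter sums and 0.070 in the mouse reporter sums. The corresponding mean correlations between plates were −0.21, −0.063, −0.021, −0.021 and −0.086. Taking out the group means pushes correlations between plates below 0, most with few plates. The values between plates therefore do not show that the block was needed. The mouse regions came from separate plates and had no block.

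The 15 comparisons, their test, the 36 gene lists (20 human, 16 mouse) and the rule for naming genes were fixed before the data were examined. Tests added later are named as such where they appear. For each comparison the rule names up to 8 genes with the largest rise and 8 with the largest fall among genes with an adjusted p below 0.05, an average log2 CPM (footprints scaled to a common library size) of at least 5 and the same direction on every plate. It adds up to 3 members of each gene list with the smallest p. CDT1 and GMNN were always looked up, as were ASNS, DDIT3, CHAC1 and ATF4 in the starvation plates. Pseudogenes and unnamed identifiers were counted but not named.

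Gene lists were tested with camera from limma 3.58.1, which asks whether a list moved more than the other genes, with a preset correlation of 0.01 between genes. The same test with a correlation estimated from the data and limma's fry were run beside it, all adjusted over the lists of one comparison. A median log2 difference over a list describes its members and carries no error of its own. Log2 differences carry edgeR's standard error, and per-plate values are log2 CPM with a prior count of 2. A gene with 0 counts in one population is given as a lower bound, with 3 counts in place of 0 over the whole group. Genes per cell were compared after drawing 2000 footprints from each cell, because depth differed between populations. Shares of cells and per-cell medians were compared over plates with exact two-sided sign-flip permutation tests. Codon values were averaged per plate and population and compared over the 61 columns with limma, an addition made after the file was seen, since values alone had been planned for 2 plates. DESeq2 1.42.0 served as the other count method. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3.

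Each method was run on simulated counts drawn from the real means and depths, with 200 genes changed by known folds. Of the genes changed 2-fold, 41.8% were found in the arginine-free 6 h comparison (7546 genes tested in all). In the mitotic comparison 88.1% were found (7659 tested) and in the G0 comparison 49.3% (7666). The share found was 89.6% for the geminin reporter (4896 tested) and 59.7% for the mouse reporter (2361). It was 19.4% for distal intestine (7522) and 13.4% for medial intestine (7498). No gene was called in runs with no gene changed, and among the calls in runs with changed genes 2.70% (geminin) to 7.46% (distal) were wrong, with 6.25% for G0. All 3 gene lists moved 1.5-fold were called in the simulated arginine-free 6 h and mitotic comparisons, and 0 of 17 unmoved lists. The simulated genes were drawn independently of each other, so this run cannot tell whether the preset correlation is right for real lists. For the mouse regions, no mix of cells particular to the lone plate was simulated. The share of wrong calls there therefore does not cover errors from such a mix. Among 61 simulated codon columns, 100% of 5 columns raised by 0.5 in log2 were called, with 0.18 wrong calls per run where none was raised.

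Several points of the labels stayed unsettled. The treatment protocol speaks of arginine or lysine, while the plate layout and sample names speak of arginine and leucine, and the layout's words are used. In the codon values, the leucine codon UUA was called higher only in the medium named leucine-free. Neither lysine codon was called higher there, which goes with the layout's words. The 8 plates of the batch named MGI are labelled interphase, but the layout places G0 and mitotic cells on them as well. These plates therefore entered the reporter comparisons with their interphase cells and were an alternative in the mitotic and G0 gene comparisons. The values per cell and the cluster shares used all their populations. The KO plates carry the population name WT in the cell table, and no edited gene is named. The SR2 plates carry the words pre and post without explanation. Histone genes, ribosomal protein genes and other near-identical copies share sequence, and footprints may have been divided among copies or dropped, so single members are uncertain and the list is the firmer unit. Gene symbols listed more than once numbered 49 in the starvation table, 99 in the RPE table and 35 in the mouse table, and were kept apart by identifier.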

Results

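The series measured ribosome footprints in single cells, that is, the stretches of messenger RNA protected by translating ribosomes, counted per gene in each cell. It holds 37 plates with 4210 cells and 44521820 counted footprints. The median cell had 9417.5 footprints on 3246 genes, cells ranged from 1593 to 46327 footprints, and plate totals ranged from 207179 to 2901891. Human embryonic kidney HEK293T cells filled 1 plate in rich medium (163 cells, 1916942 footprints) and 2 plates that held rich medium beside arginine-free and leucine-free medium for 3 h and 6 h (421 cells, plate totals of 1743034 and 2467458). The retinal pigment epithelial line hTERT-RPE1 with a FUCCI reporter filled 27 plates (3276 cells, plate totals of 317656 to 2901891). FUCCI marks cell-cycle position with a green geminin fragment, present from S phase to mitosis, and a red CDT1 fragment, present mainly in G1. Of these plates, 7 held mitotic and interphase cells, 2 held G0 and interphase cells, 4 were interphase plates named KO, 6 were interphase plates named SR2 and 8 belonged to the batch named MGI. Mouse intestinal hormone-producing cells with the Neurog3Chrono reporter filled 5 proximal plates (268 cells), 1 distal plate (47 cells) and 1 medial plate (35 cells), with plate totals of 207179 to 452064. The rich-medium plate entered no comparison and had a median of 11033 footprints and 4105 genes per cell. Footprint counts on a gene rise with its messenger RNA as well as with its translation, and no RNA measurement was used here to separate them. Separate cultures or animals behind the plates are not stated, so p-values of single genes, codons and plate values measure spread between plates, which may be technical. A camera p-value sets the genes of a list against the other genes. It depends on the number of genes and the correlation assumed, so a small one does not show replication over plates.

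The starvation plates asked how cells change translation when an amino acid that they need is missing. On these plates 93 cells had been without arginine for 3 h and 62 for 6 h, 110 without leucine for 3 h and 92 for 6 h, and 64 were in rich medium. Median genes per cell were 3744, 3928, 4282.5, 3565.5 and 3392.5 in that order. After 2000 footprints were drawn per cell the medians were 1411, 1394, 1405, 1406 and 1377, with 1, 0, 0, 2 and 2 shallower cells left out.

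Without arginine for 3 h, HEK293T cells translated the amino acid response more. The genes that rose included ATF4, the transcription factor that drives this response, ASNS, which makes asparagine, CTH, which makes cysteine, CHAC1, which degrades glutathione, and DDIT4, a brake on the growth kinase mTOR. STC2, a secreted stress protein, IFRD1, a transcriptional coregulator, and TXNIP, which limits glucose uptake, rose as well. Amino acid transporters followed, with the cystine carrier SLC7A11, its partner chain SLC3A2 and the neutral amino acid carrier SLC38A2. Histone genes that package new DNA rose together, H3C2 and H4C5 among them, and so did MT-CO3, MT-CO2 and MT-CYB, the respiratory chain genes of mitochondrial DNA. XBP1, a regulator of the unfolded protein response, and the early response factors JUN and KLF10 rose too. Cytosolic chaperones fell, including HSPA8, its cochaperones DNAJA1 and DNAJB1, and HSP90AB1. So did the elongation factor EEF2, the poly(A)-binding protein PABPC1, the ribosomal stalk protein RPLP2, the cytoskeletal genes TUBB4B and VIM, the glycolytic enzymes ALDOA and GPI, the methionine adenosyltransferase MAT2A and the iron importer TFRC.

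In numbers, 130 genes were higher and 218 lower at 3 h of 7776 tested, and 346 of these 348 had the same direction on both plates (edgeR, adjusted p below 0.05). HSPA8 dropped from 4129 ± 218 to 357.5 ± 25.6 CPM (SD, n = 2 plates; log2 difference −3.59 ± 0.16 SE, edgeR adjusted p = 2.3e-19). H3C2 rose from 1212 ± 25.9 to 4944 ± 60.8 CPM (1.97 ± 0.12, edgeR adjusted p = 2.7e-15). STC2 rose by 2.79 ± 0.23 (edgeR adjusted p = 1.1e-11), CHAC1 by 2.88 ± 0.50 (1.3e-04), ATF4 by 1.42 ± 0.22 (1.6e-05) and ASNS by 0.84 ± 0.14 (6.1e-05). MT-CO3 rose from 610.3 ± 18.6 to 1392 ± 319 CPM. CDT1 at 0.48 and GMNN at −0.46 did not pass, and DDIT3 was too rare to be tested.

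As groups at 3 h without arginine, all 39 histone genes were higher (39 adjusted over the list alone; median 1.33, camera adjusted p = 2.6e-108). Of 21 amino acid response genes 12 were higher and 0 lower (17 adjusted over the list alone; median 1.16, camera adjusted p = 3.7e-20). The 15 transporters had 4 higher (5 adjusted over the list alone; camera adjusted p = 2.2e-04). The 19 cytosolic chaperones had 11 lower (16 adjusted over the list alone; median −0.39, camera adjusted p = 2.9e-23) and the 19 translation factors 12 lower (14 lower and 1 higher adjusted over the list alone; −0.53, camera adjusted p = 3.6e-15). The 20 cytoskeletal genes had 5 lower (9 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.5e-07) and the 16 glycolytic genes 5 lower (6 adjusted over the list alone; camera adjusted p = 4.5e-05). These 7 calls held with an estimated correlation. The 13 mitochondrially encoded genes had 10 higher (12 higher and 1 lower adjusted over the list alone; median 0.94, camera adjusted p = 4.3e-18, adjusted p = 0.086 with an estimated correlation). The 66 ribosomal protein genes had 14 lower (19 lower and 2 higher adjusted over the list alone; median −0.22, camera adjusted p = 1.7e-05, adjusted p = 0.32 with an estimated correlation). The 7 immediate early genes had 2 higher (2 adjusted over the list alone; camera adjusted p = 0.0087, adjusted p = 0.32 with an estimated correlation). Aminoacyl-tRNA synthetases, lysosomal genes, cholesterol synthesis, endoplasmic reticulum stress, matrix, G2 and mitosis, nuclear-encoded respiratory chain, p53 targets, YAP targets and DNA replication passed in neither direction (camera adjusted p from 0.0795 to 0.787). The DNA replication list had a median of −0.0036 and a mean of 0.040, which differ in sign.

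After 6 h without arginine, IFRD1, STC2, CHAC1, DDIT4, CTH, ASNS, ATF4 and SLC7A11 were again higher than in rich medium, as were TRIB3, a pseudokinase that feeds back on ATF4, and GADD45A, which acts in growth arrest. The single transfer RNA synthetases YARS1, FARSB and SARS1 were higher, although their list as a whole did not pass. UNG, which removes uracil from DNA, and the nucleotide enzyme TK1 were higher too. The cholesterol synthesis genes SQLE and HMGCS1 fell. Single mitotic genes fell as well, among them CCNB1, the cyclin that starts mitosis, the proliferation marker MKI67 and the kinesin KIF20A, while their list was not called with an estimated correlation (adjusted p = 0.18). HSPA8, DNAJA1, TFRC, the tubulins TUBA1C and TUBB4B and the glycolytic enzyme PKM stayed low.

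At 6 h, 232 genes were higher and 319 lower than in rich medium, 549 of the 551 with the same direction on both plates. HSPA8 stood at 175.1 ± 84.8 CPM (−4.50 ± 0.18). All 39 histone genes were again higher (39 adjusted over the list alone; median 1.62, camera adjusted p = 2.5e-107). The amino acid response had 14 of 21 higher (19 adjusted over the list alone; median 1.15, camera adjusted p = 2.3e-21), the transporters 6 of 15 (8 adjusted over the list alone; 4.4e-05), the chaperones 13 of 19 lower (16 adjusted over the list alone; 4.2e-22), the cytoskeletal genes 7 of 20 lower (11 adjusted over the list alone; 1.6e-10) and the glycolytic genes 4 of 16 lower (8 adjusted over the list alone; 2.4e-04). These held with an estimated correlation. Of 19 cholesterol genes 7 were lower (9 adjusted over the list alone; median −0.49, camera adjusted p = 1.0e-05, adjusted p = 0.051 with an estimated correlation). Of 52 G2 and mitosis genes 17 were lower (20 adjusted over the list alone; median −0.41, camera adjusted p = 2.6e-13, adjusted p = 0.18 with an estimated correlation). The translation factors had 10 of 19 lower (14 adjusted over the list alone; camera adjusted p = 1.1e-10, adjusted p = 0.058 with an estimated correlation). The mitochondrially encoded genes had 5 of 13 higher (7 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.6e-07, adjusted p = 0.23 with an estimated correlation). DNA replication had 5 of 38 higher and 1 lower (6 and 1 adjusted over the list alone; camera adjusted p = 6.3e-04, adjusted p = 0.14 with an estimated correlation). Matrix (0.0274) and the nuclear-encoded respiratory chain (0.033) passed with camera, with adjusted p = 0.24 and adjusted p = 0.376 with an estimated correlation. The respiratory chain medians on the plates, −0.081 and 0.246, differed in sign. The 18 synthetases (5 higher, camera adjusted p = 0.0781) and the 66 ribosomal protein genes (3 higher, 8 lower, median −0.076, camera adjusted p = 0.216) did not pass. The 6 h sums rest on 62 arginine-free and 64 rich cells, and DESeq2 called fewer genes throughout, 142 at 3 h and 193 at 6 h.

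Without leucine, HEK293T cells raised the same kind of stress genes and lowered the protein synthesis machinery itself. At 3 h STC2, CHAC1, TXNIP, IFRD1, DDIT4, CTH, ASNS, ATF4 and XBP1 rose, together with SLC38A2, SLC7A11 and the cationic amino acid carrier SLC7A1. Histone genes such as H4C3 and H3C2 and the mitochondrially encoded MT-CO3 rose. Ribosomal protein genes fell, among them RPS6, RPS19 and RPLP2, and so did EEF1A1, which brings charged transfer RNAs to the ribosome, and EEF2. HSPA8, DNAJA1, TUBB4B, GAPDH, MKI67 and CCNB1 also fell. At 6 h TRIB3, the synthetases GARS1, YARS1 and MARS1, and SLC3A2 were higher too. The translation-linked protein TPT1, the cholesterol enzymes HMGCS1, IDI1 and SQLE, the chaperonin subunit CCT6A, the endoplasmic reticulum chaperone CALR, TFRC and the mitotic activator CDC20 were lower.

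The leucine comparisons called 70 genes higher and 97 lower at 3 h, and 174 and 239 at 6 h. EEF1A1 dropped by 1.60 ± 0.19 at 3 h, and RPS19 changed by −1.28 ± 0.14 at 6 h. HSPA8 changed by −2.24 ± 0.14 at 3 h and −2.69 ± 0.15 at 6 h. ASNS rose from 431.5 ± 57.7 to 1194 ± 38.6 CPM at 6 h (1.41 ± 0.14). Of 66 ribosomal protein genes 28 were lower at 3 h (46 adjusted over the list alone; median −0.54, camera adjusted p = 5.4e-46). At 6 h 40 were lower and 1 higher (51 and 2 adjusted over the list alone; median −0.67, camera adjusted p = 3.4e-43). Translation factors had 8 of 19 lower at 3 h (13 adjusted over the list alone; camera adjusted p = 1.5e-21) and 11 at 6 h (15 lower and 1 higher adjusted over the list alone; 7.7e-18). The amino acid response had 8 of 21 higher at 3 h (17 adjusted over the list alone; median 0.88, camera adjusted p = 1.4e-21) and 16 at 6 h (18 adjusted over the list alone; median 1.22, 9.7e-25). The transporters had 5 of 15 higher at 3 h (6 adjusted over the list alone; 2.1e-07) and 7 at 6 h (9 adjusted over the list alone; 3.1e-10). These calls and the cytoskeletal calls, with 5 of 20 genes lower at 3 h and 9 at 6 h (8 and 11 adjusted over the list alone), held with an estimated correlation.

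Other leucine lists depended on the correlation assumed. The chaperones had 6 of 19 lower at 3 h (10 adjusted over the list alone; camera adjusted p = 8.2e-16, adjusted p = 0.051 with an estimated correlation). At 6 h 15 were lower (16 adjusted over the list alone; 3.5e-25), which held. Of 39 histone genes 18 were higher at 3 h (30 adjusted over the list alone; median 0.66, camera adjusted p = 2.3e-35, adjusted p = 0.088 with an estimated correlation). At 6 h 27 were higher (33 adjusted over the list alone; median 0.87, camera adjusted p = 4.5e-43, adjusted p = 0.051 with an estimated correlation). The mitochondrially encoded genes had 6 of 13 higher at both times, with camera adjusted p = 2.0e-11 and 3.3e-08, and adjusted p = 0.17 and adjusted p = 0.21 with an estimated correlation. Cholesterol synthesis passed only at 6 h, with 4 of 19 lower (8 adjusted over the list alone; 4.8e-06, adjusted p = 0.050 with an estimated correlation). Glycolysis passed at 6 h (0.0017, adjusted p = 0.051 with an estimated correlation), as did the synthetases, with 3 of 18 higher and 1 lower (0.0087, adjusted p = 0.19 with an estimated correlation). G2 and mitosis passed at 3 h with 4 of 52 lower (9.7e-04, adjusted p = 0.53 with an estimated correlation) and not at 6 h (camera adjusted p = 0.231). At 3 h the medians of this list on the plates, 0.073 and −0.308, differed in sign. The remaining lists passed at neither time. DESeq2 called 82 genes at 3 h and 149 at 6 h.

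**Figure D1:**
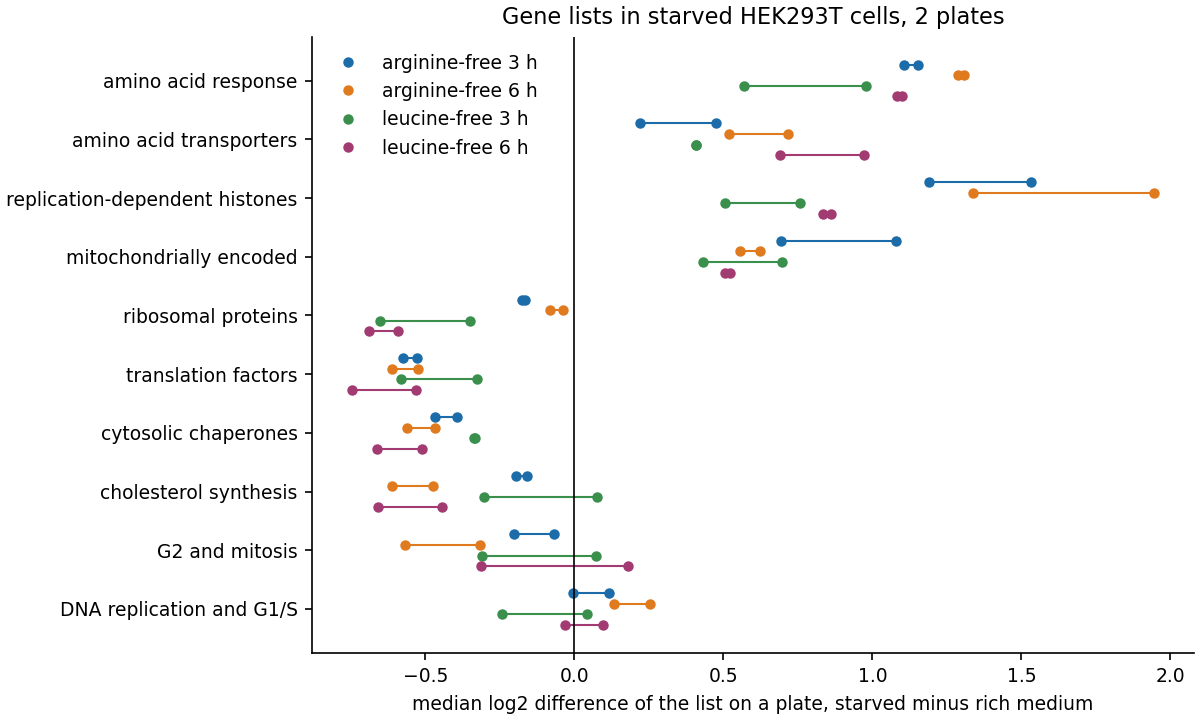
Median log2 difference from rich medium of 10 gene lists on each of the 2 starvation plates (points; a line joins the plates), by medium and time. The amino acid response lies above 0 on both plates in every medium, from 0.57 on the lowest plate (leucine-free 3 h) to 1.31 on the highest (arginine-free 6 h).

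The direct comparison of both media asked where cells without arginine differed from cells without leucine. At 3 h, histone genes were higher without arginine than without leucine, among them H3C7, H4C4, H4C5 and H3C2, as were the ribosomal protein genes RPL28, RPS16 and RPL3, the start-site factor EIF5, EEF1A1, XBP1 and the mitochondrial MT-CYB and MT-ND4. With an estimated correlation neither list passed (adjusted p = 0.11 for histones and 0.15 for ribosomal proteins). The topoisomerase TOP2B, the chaperones HSPA8, DNAJA1 and HSP90B1, the histone-binding protein PTMA, the initiation factor EIF3A and the carrier SLC7A1 were lower. At 6 h H3C2, H4C4, RPL28, RPS19, EIF5, EEF1A1, the stress factor ATF3, TK1 and the respiratory chain subunits NDUFB10 and UQCRQ were higher without arginine. HSPA8, TOP2B, the mitotic genes KIF20A, INCENP, MKI67 and CCNB1, the folate enzyme ALDH1L2, GARS1, SLC7A1, EIF3A and the autophagy kinase ULK1 were lower. ASNS, ATF4 and CHAC1 differed between the media at neither time.

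At 3 h 70 genes were higher and 47 lower without arginine than without leucine, all 117 in the same direction on both plates. At 6 h 113 were higher and 70 lower. H4C4 differed by 1.36 ± 0.13 at 3 h (edgeR adjusted p = 4.3e-09), RPL28 by 1.36 ± 0.15 at 6 h (edgeR adjusted p = 8.3e-08) and HSPA8 by −1.81 ± 0.20 at 6 h. Histone genes had 34 of 39 higher at 3 h (39 adjusted over the list alone; median 0.79, camera adjusted p = 4.3e-98, adjusted p = 0.11 with an estimated correlation). At 6 h 37 were higher (38 adjusted over the list alone; median 0.81, camera adjusted p = 1.4e-76, adjusted p = 0.082 with an estimated correlation). Ribosomal protein genes had 17 of 66 higher at 3 h (30 adjusted over the list alone; median 0.34, camera adjusted p = 2.1e-24, adjusted p = 0.15 with an estimated correlation). At 6 h 33 were higher (43 higher and 1 lower adjusted over the list alone; median 0.57, camera adjusted p = 8.3e-45, adjusted p = 0.082 with an estimated correlation). G2 and mitosis had 10 of 52 lower at 6 h (20 adjusted over the list alone; median −0.49, camera adjusted p = 4.0e-16, adjusted p = 0.21 with an estimated correlation) and did not pass at 3 h (0.224). The amino acid response passed narrowly at 3 h with 0 genes called (median 0.17, camera adjusted p = 0.027, adjusted p = 0.35 with an estimated correlation) and not at 6 h (median 0.066, 0.699). No list in either direct comparison passed with an estimated correlation. DESeq2 called 62 genes at 3 h and 92 at 6 h.

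Between 3 h and 6 h few single genes moved. Without arginine, the cold-inducible RNA-binding protein CIRBP rose by 0.75 ± 0.15 (edgeR adjusted p = 0.030), and the mitotic kinase PLK1 (−1.19), CCNB1 (−0.90) and KCTD12 (−1.52) fell, the only 4 genes called by edgeR. Without leucine 8 genes rose, namely D2HGDH, the glycine carrier SLC6A9, CTH, ASNS, CIRBP and the histones H2AC8, H2AC20 and H2BC11. There 9 genes fell, with HMGCS1, TFRC and the chaperone partners DNAJA1, DNAJA2 and FKBP4 among them. DESeq2 called 0 genes in both, against 134 and 102 at an unadjusted p below 0.05, where edgeR had 688 and 764. As a group, G2 and mitosis genes were lower at 6 h than at 3 h without arginine (2 of 52 called, 20 adjusted over the list alone; median −0.50, camera adjusted p = 3.9e-21, adjusted p = 0.23 with an estimated correlation). Cholesterol genes were lower at 6 h without leucine (1 of 19 called, 8 adjusted over the list alone; median −0.53, camera adjusted p = 3.3e-10, adjusted p = 0.11 with an estimated correlation).

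The codon values of the starvation plates give, per cell, how often footprints sat on each codon compared with rich medium. Without arginine the arginine codons CGC and CGU rose most of all 61 codons, and the other arginine codons moved little. CGC rose by 0.73 ± 0.051 in log2 at 3 h (limma adjusted p = 5.0e-10; plates 0.70 and 0.77) and by 0.87 ± 0.051 at 6 h (limma adjusted p = 2.4e-11; plates 0.96 and 0.78). CGU rose by 0.55 at 3 h and 0.58 at 6 h. AGA rose by 0.18 (limma adjusted p = 0.0027) and CGA by 0.095 (limma adjusted p = 0.041) at 6 h only. CGG, at 0.048 and 0.041, and AGG, at 0.088 and 0.041, were not called at either time. Without leucine the leucine codon UUA rose by 0.36 at both times (limma adjusted p = 0.0011 and 5.1e-04), with plate values of 0.51 and 0.20 at 3 h and 0.31 and 0.40 at 6 h. The leucine codons CUA, by 0.15 and 0.10, and CUC, by 0.12 at 3 h only, were called too. Both also rose without arginine, CUA by 0.16 and 0.11 and CUC by 0.18 and 0.14. In leucine-free medium CGC stood at 0.082 at 3 h (limma adjusted p = 0.29) and rose by 0.16 at 6 h (limma adjusted p = 0.024), when the arginine codons CGA (0.14) and CGG (0.098) were called as well. The cysteine codon UGC rose in all 4 starved groups, by 0.22 to 0.30, and the histidine codon CAU fell in all 4. In total 17 codons rose and 9 fell without arginine at 3 h, 20 and 10 at 6 h, 9 and 1 without leucine at 3 h, and 12 and 8 at 6 h. With medians over cells in place of means, leucine-free cells had only 2 called codons at 3 h and 10 at 6 h. The test rests on 2 plates and was added after the values had been seen.

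**Figure D2:**
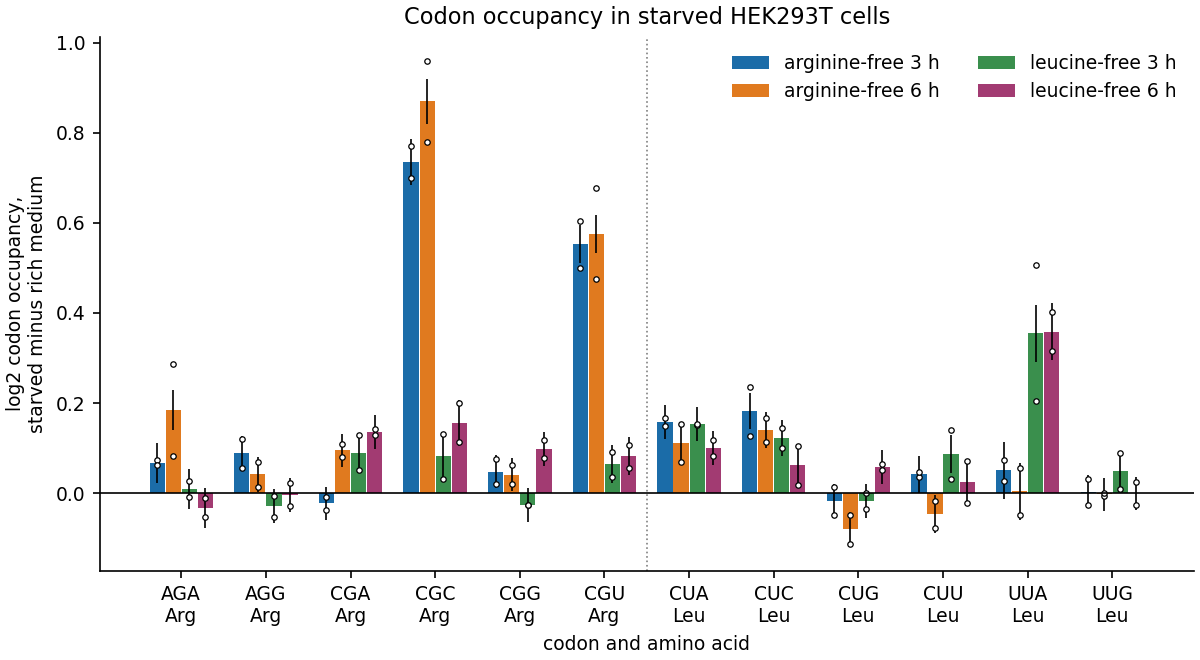
Log2 codon occupancy in starved minus rich medium for the 6 arginine and 6 leucine codons, as means over 2 plates (bars) with limma's standard error (lines) and the plate values (open points). CGC reached 0.87 and CGU 0.58 in arginine-free medium at 6 h, and UUA reached 0.36 in leucine-free medium.

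The mitotic plates asked which genes are translated in cells shaken off during mitosis, compared with interphase cells of the same plates. The cells were 288 mitotic and 525 interphase cells on 7 plates. Genes that run mitosis rose, namely CCNB1, the kinases PLK1, NEK2 and AURKA, the spindle proteins ASPM and CKAP2, the kinesin KIF20A and ANLN, which builds the division furrow. VIM, an intermediate filament, the tubulins TUBB4B and TUBA1C, and TK1 rose with them. So did the chaperones HSPA8 and HSPH1, the chaperonin subunit CCT5, the ribosome-bound RACK1, TPT1, RPS6, the survival factor MCL1, the serine enzyme SHMT2, the ATP synthase subunit ATP5F1B and MT-CO3. Histone genes almost vanished, with H3C1, H2BC18, H1-2 and H2AC6 as examples, and with them fell the S-phase genes UNG and CCNE2. Targets of p53 fell (CDKN1A, which halts the cycle, MDM2, which degrades p53, and PLK2), as did matrix genes (FN1, VCAN, THBS1 and the hyaluronan enzyme CEMIP) and targets of YAP (CCN1, CCN2, ANKRD1). MYC, the endoplasmic reticulum chaperone HSP90B1, the lysosomal CTSD and PSAP, SLC38A2, DDIT4, STC2 and the helicase EIF4A2 fell too.

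Of 7795 genes, 1994 were higher and 2008 lower in mitosis, and 2864 of these 4002 had the same direction on all 7 plates. CCNB1 (hg38 chromosome 5, 69167010 to 69178245) rose from 84.5 ± 37.5 to 1223 ± 86.5 CPM (SD, n = 7 plates; log2 difference 3.90 ± 0.11 SE, edgeR adjusted p = 1.3e-36). H1-2 dropped from 1237 to 18.9 CPM (−5.96 ± 0.12), and CDKN1A changed by −3.10 ± 0.14. H3C1 and H2BC18 had 0 counts in mitotic cells and were at least 56.0-fold and at least 54.2-fold lower over the group. VIM rose from 15170 to 41930 CPM. GMNN rose by 0.42, and CDT1 by 0.25 (edgeR adjusted p = 0.023), the latter on 5 of 7 plates and without a DESeq2 call.

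All 53 G2 and mitosis genes were higher in mitotic cells (53 adjusted over the list alone; median 2.73, camera adjusted p = 1.2e-61) and all 41 histone genes lower (41 adjusted over the list alone; median −5.24, or −4.96 with 4 absent genes at their bound, camera adjusted p = 8.1e-35). Matrix genes had 23 of 29 lower and 1 higher (25 and 1 adjusted over the list alone; median −0.61, 1.3e-15), p53 targets 12 of 16 lower (12 adjusted over the list alone; median −1.34, 4.1e-05) and YAP targets 10 of 13 lower and 1 higher (10 and 1 adjusted over the list alone; median −0.54, 3.5e-06). Chaperones had 16 of 19 higher (18 adjusted over the list alone; median 0.49, 4.8e-09). These 6 calls held with an estimated correlation. Ribosomal protein genes had 41 of 65 higher and 1 lower (42 and 2 adjusted over the list alone; median 0.39, camera adjusted p = 3.8e-07, adjusted p = 0.071 with an estimated correlation). Translation factors had 15 of 19 higher and 1 lower (16 and 1 adjusted over the list alone; median 0.55, camera adjusted p = 5.3e-07, adjusted p = 0.079 with an estimated correlation). Endoplasmic reticulum stress had 7 of 14 lower (7 adjusted over the list alone; 0.0023, adjusted p = 0.098 with an estimated correlation) and the immediate early genes 8 of 13 lower and 2 higher (8 and 2 adjusted over the list alone; 0.043, adjusted p = 0.10 with an estimated correlation). The mitochondrially encoded genes had 9 of 13 higher and 1 lower (9 and 1 adjusted over the list alone; 0.010, adjusted p = 0.20 with an estimated correlation). Cytoskeletal genes had 12 of 23 higher and 8 lower (0.028, adjusted p = 0.18 with an estimated correlation). DNA replication (12 of 36 higher, 17 lower, camera adjusted p = 0.0885), the amino acid response, transporters, synthetases, lysosome, cholesterol synthesis, glycolysis and the nuclear-encoded respiratory chain did not pass. The amino acid response and glycolysis lists had medians of −0.15 and −0.037 while camera pointed up.

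Over the 7 plates and the 8 MGI plates together, mitotic cells had a plate mean of 9900 footprints per cell against 9212.5 in interphase (688 more, higher on 13 of 15 plates, exact two-sided sign-flip permutation p = 0.0070, adjusted 0.012 over 10 tests). At 2000 footprints per cell they had 1162 against 1158.5 genes (exact p = 0.32), and no RPE cell was left out. By plate medians the difference was 13.6 genes on the first plates (higher on 7 of 7, exact p = 0.016, the smallest possible) and −5.45 on the MGI plates (higher on 2 of 8, exact p = 0.10). By plate means it was 30.2 and 11.8, higher on all plates of both, so the direction in the MGI plates depends on the summary. Unthinned they had 3197 against 3112 genes (exact p = 0.091). The authors' cluster 6 held 98.4% ± 1.67 of mitotic and 0.848% ± 1.10 of interphase cells (SD, n = 15 plates, exact two-sided permutation p = 6.1e-05, the smallest possible). It was picked for holding more mitotic cells than any other cluster, which favours a higher mitotic share, so the p-value adds no support.

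G0 cells, kept in culture for longer, were compared with interphase cells to ask what resting cells translate, with 87 and 98 cells on 2 plates. Matrix and secreted genes rose, among them COL1A1, the main collagen, SPARC, which binds collagen, VCAN, the collagen receptor ITGA11, the protease inhibitor TFPI2, the secretory granule protein SCG2 and the growth factor TGFB2. The xenobiotic enzyme CYP1B1, the antigen-presenting HLA-B, the arrest gene CDKN1A, PLK2 and JUNB rose as well. Genes of the secretory pathway (HSP90B1, PDIA3, CALR), of the lysosome (HEXA, LAMP2, PSAP) and the stress gene STC2 rose. On the MGI plates LAMP2 did not rise, and TFPI2 rose less or fell more. Proliferation genes fell, with MKI67, the checkpoint kinase BUB1, KIF20A, ANLN and PRC1 for division, RRM2 and TK1 for nucleotides, MCM7 for replication, and the histones H3C2 and H3C3. Ribosomal protein genes (RPS3, RPL13), the sterol enzyme ACAT2, ACTB, TUBB4B, GAPDH, HSP90AA1, CCT5, the growth-linked factor FOSL1, CCN1 and CCNG1 fell, and so did GMNN and CDT1.

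Of 7795 genes 978 were higher and 1101 lower in G0, 2068 of these 2079 in the same direction on both plates. COL1A1 rose from 182.9 ± 70.9 to 1319 ± 113 CPM (SD, n = 2 plates; 3.03 ± 0.15, edgeR adjusted p = 1.4e-23). MKI67 had 868.3 CPM in interphase and 0 counts in G0, at least 449-fold lower over the group, and H3C2 changed by −6.70 ± 0.25. On the MGI plates MKI67, BUB1 and KIF20A fell less. All 53 G2 and mitosis genes were lower (53 adjusted over the list alone; median −5.19, or −4.68 with 14 absent genes at their bound, camera adjusted p = 1.5e-29, adjusted p = 0.069 with an estimated correlation). DNA replication had 35 of 36 lower (35 adjusted over the list alone; median −2.43, 2.5e-24) and histone genes 39 of 41 (40 adjusted over the list alone; median −3.51, 1.3e-43). Matrix had 27 of 29 higher and 2 lower (27 and 2 adjusted over the list alone; median 1.14, 4.1e-32), endoplasmic reticulum stress 11 of 14 higher (12 adjusted over the list alone; 0.71, 1.4e-10) and lysosome 11 of 16 higher (11 adjusted over the list alone; 0.59, 1.3e-07). Ribosomal protein genes had 43 of 65 lower (47 adjusted over the list alone; median −0.60, 9.1e-16) and cytoskeletal genes 14 of 23 lower and 3 higher (14 and 5 adjusted over the list alone; −0.55, 2.8e-09). These 7 held with an estimated correlation.

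Further lists moved in G0 with the preset correlation only. Translation factors had 11 of 19 lower (13 adjusted over the list alone; median −0.48, camera adjusted p = 2.8e-05, adjusted p = 0.098 with an estimated correlation), chaperones 11 of 19 lower (11 adjusted over the list alone; 1.7e-04, adjusted p = 0.12 with an estimated correlation) and cholesterol synthesis 10 of 21 lower (13 adjusted over the list alone; 8.1e-04, adjusted p = 0.059 with an estimated correlation). Glycolysis (0.0015), the nuclear-encoded respiratory chain (0.0047) and the synthetases (0.035) were lower, with adjusted p = 0.059, 0.32 and 0.28 with an estimated correlation. Targets of p53 had 8 of 16 higher and 1 lower (8 and 1 adjusted over the list alone; 0.013, adjusted p = 0.059 with an estimated correlation). The amino acid response, transporters, YAP targets, immediate early and mitochondrially encoded genes did not pass. For the immediate early genes (median 0.10, mean −0.11) and the mitochondrially encoded genes (median 0.018, mean −0.078) the median and mean differed in sign. The comparison has 2 plates, and DESeq2 called 1004 genes. With plate 11 or plate 12 left out, 1 G0 sum remains and the spread comes only from the mitotic plates of the fit. Such a run cannot judge the comparison.

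Over these plates and the 8 MGI plates, G0 cells had a plate mean of 9395 footprints per cell against 10769 in interphase (exact two-sided sign-flip permutation p = 0.0059, adjusted 0.012, n = 10 plates). On the MGI plates the ratio was 0.810, and on the 2 first plates 1.02 by medians and 0.957 by means over cells. They also had fewer genes per cell, 2944 against 3352 and 1099.6 against 1165 at equal depth, on all 10 plates (exact p = 0.0020, the smallest possible, adjusted 0.0065). Their mitochondrial share was 0.332% against 0.405%, again lower on all 10 plates. The authors' cluster 7 held 81.9% ± 6.95 of G0 and 16.9% ± 1.98 of interphase cells (SD, n = 10 plates, exact permutation p = 0.0020). This cluster too was picked for holding the most cells of the tested population, so the p-value adds no support.

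**Figure D3:**
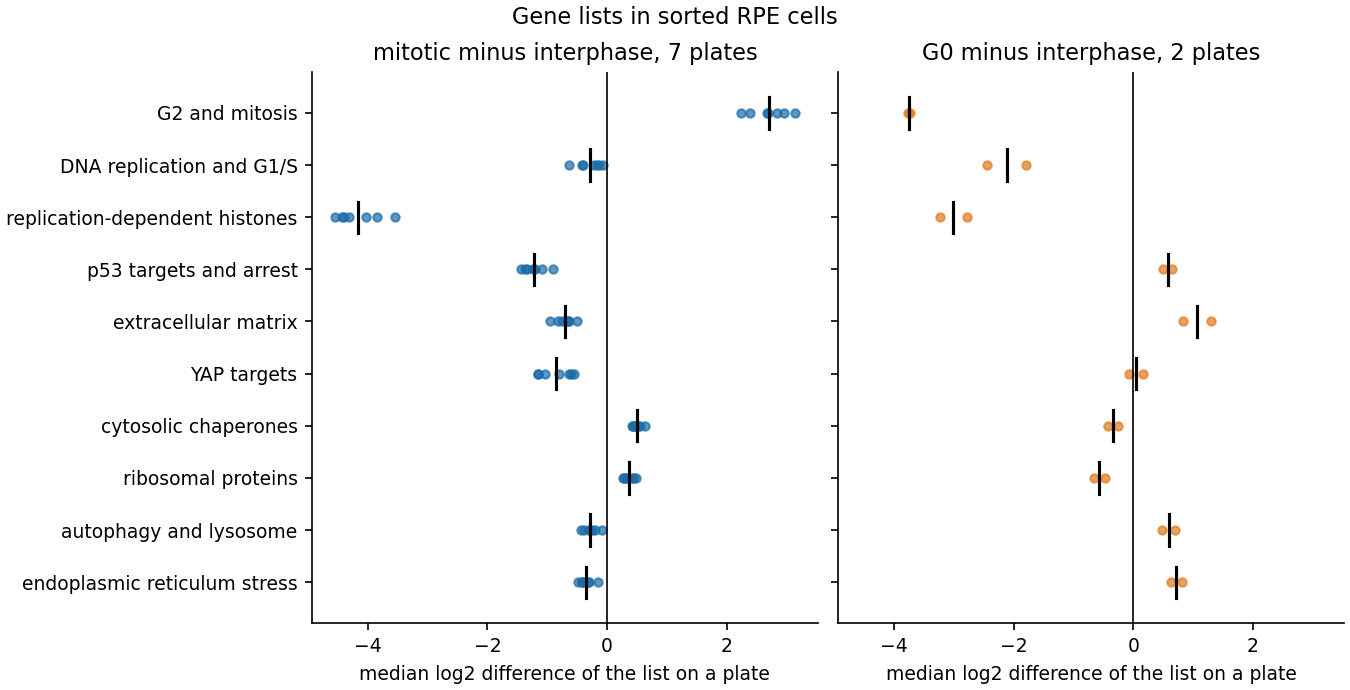
Median log2 difference of 10 gene lists on each plate (points) and the mean over plates (black lines), for mitotic minus interphase cells on 7 plates and G0 minus interphase cells on 2 plates. G2 and mitosis genes lie between 2.25 and 3.13 on the mitotic plates, and histone genes between −4.54 and −3.55.

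The FUCCI reporter orders interphase cells by cycle position without use of the footprints, and the upper and lower terciles of each colour were compared within 27 plates. Cells with a high geminin signal had more footprints on histone genes (H2BC14, H1-5, H3C3), on the division genes CDK1, UBE2C and TOP2A, and on the replication genes MCM4, FEN1 and POLE. FOSL1, HSPA8, TUBA1C, RPL32, the folate enzyme MTHFD2, CDT1 and GMNN rose by less. The transcriptional regulators TSC22D1 and MXD4, the phosphatase DUSP4, the vessel growth factor VEGFA, COL1A1, the matrix protease MMP2, CTSD, PSAP, STC2, PLK2 and the respiratory subunit NDUFB4 fell. Cells with a high CDT1 signal had more footprints on matrix and adhesion genes (THBS1, FN1, FBN1, CCDC80, ITGA11), on the peptidase CPA4, on TGFB2 and on the YAP targets CCN2 and ANKRD1. CDKN1A, ZMAT3 and PLK2 of the p53 response, the lysosomal CTSD and GRN, HSPA5, MT-CO1 and EIF4A2 rose too. KIF20A, PLK1, CCNB1, CCNB2, the histones H4C4 and H4C3, RRM1, TK1, TUBA1B, TUBB4B, the splicing factor HNRNPA1, the serine enzyme PHGDH, FOSL1 and CCT5 fell.

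The geminin comparison called 1232 genes higher and 1327 lower of 4991, and the CDT1 comparison 1285 and 1251 of 4806. Only 231 of 2559 and 261 of 2536 had the same direction on all 27 plates. H3C3 rose from 67.0 to 2089 CPM with geminin (4.95 ± 0.11), and CCNB1 changed by −4.01 ± 0.11 and THBS1 by 1.66 ± 0.07 with CDT1. CDT1 and GMNN footprints, at 0.063 and 0.019, did not differ with the CDT1 reporter. With geminin, all 40 histone genes (40 adjusted over the list alone; median 4.18, camera adjusted p = 8.6e-62) and all 33 DNA replication genes (33 adjusted over the list alone; median 1.498, 2.5e-25) were higher, which held with an estimated correlation. G2 and mitosis had 47 of 50 higher (47 adjusted over the list alone; median 1.88, camera adjusted p = 8.7e-24, adjusted p = 0.13 with an estimated correlation) and ribosomal protein genes 43 of 60 (43 adjusted over the list alone; median 0.23, 2.0e-07, adjusted p = 0.30 with an estimated correlation). Lysosome had 12 of 13 lower (12 adjusted over the list alone; 9.0e-05, adjusted p = 0.091 with an estimated correlation), the nuclear-encoded respiratory chain 32 of 69 lower (32 adjusted over the list alone; median −0.16, 3.4e-04, adjusted p = 0.091 with an estimated correlation) and matrix 15 of 26 lower and 3 higher (16 and 3 adjusted over the list alone; 6.0e-04, adjusted p = 0.32 with an estimated correlation). Synthetases (11 of 18 higher), translation factors (11 of 19 higher), mitochondrially encoded genes (8 of 12 higher) and chaperones (11 of 19 higher) passed with camera (adjusted p from 0.0013 to 0.033) and not with an estimated correlation (adjusted p = 0.294 to 0.341). The cytoskeletal list, median −0.024 and mean 0.084, and the other lists did not pass.

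With CDT1, G2 and mitosis had 49 of 50 lower (49 adjusted over the list alone; median −2.58, camera adjusted p = 1.4e-50), matrix 25 of 26 higher (25 adjusted over the list alone; 0.82, 2.5e-19) and YAP targets 10 of 12 higher and 1 lower (11 and 1 adjusted over the list alone; 0.52, 5.0e-05). These 3 held with an estimated correlation. Histone genes had 39 of 40 lower (40 adjusted over the list alone; median −0.92, 1.0e-10, adjusted p = 0.32 with an estimated correlation). Mitochondrially encoded genes had 13 of 13 higher (13 adjusted over the list alone; 5.6e-04, adjusted p = 0.11 with an estimated correlation), endoplasmic reticulum stress 9 of 11 higher (9 adjusted over the list alone; 8.0e-04, adjusted p = 0.11 with an estimated correlation) and lysosome 8 of 12 higher and 2 lower (6.8e-04, adjusted p = 0.14 with an estimated correlation). Chaperones had 13 of 19 lower and 1 higher (0.0025, adjusted p = 0.11 with an estimated correlation), ribosomal protein genes 23 of 60 lower and 1 higher (0.0035, adjusted p = 0.48 with an estimated correlation) and p53 targets 7 of 11 higher and 1 lower (0.026, adjusted p = 0.11 with an estimated correlation). DNA replication, glycolysis (median −0.0011, mean 0.045) and the remaining lists did not pass. The SR2 plates alone called 456 genes with geminin and 779 with CDT1.

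**Figure D4:**
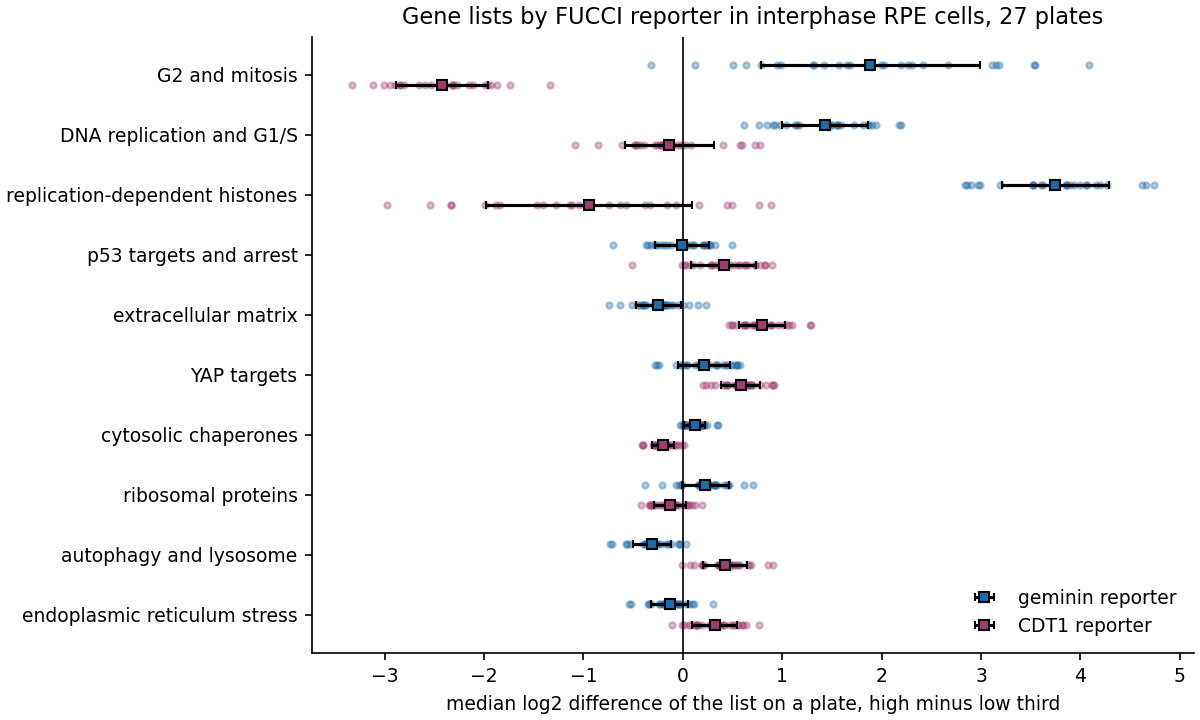
Median log2 difference between upper and lower reporter terciles of 10 gene lists on each of 27 RPE plates (points), with the mean and SD over plates (squares and bars), for the geminin and CDT1 reporters. The medians in the fit were 4.18 with geminin and −0.92 with CDT1 for histone genes, and 1.88 and −2.58 for G2 and mitosis genes.

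The mouse plates asked how hormone-producing cells differ along the intestine. The distal plate had more footprints on the hormones neurotensin (Nts), peptide YY (Pyy) and secretin (Sct) than the proximal plates, with Nts in only 3 of 47 distal cells. It also had more on Pla2g4c, a phospholipase, Naaladl1, a peptidase, and the antimicrobial genes Reg3b, Reg3g, Ang4, Itln1 and Mmp7. DESeq2 did not call Reg3g, Ang4 and Itln1 of these, nor Creld2, Foxa2, Nkx2-2 and Rab3c of the distal genes named next. It gave no adjusted p for Reg3b, Onecut2, Fabp1 and Cdc20. Goblet cell genes (Clca1, Agr2, Guca2a), Krt20 and the secretory pathway genes Pdia3 and Creld2 were higher, as was Rpl8. These go with a different mix of cells, since the authors' cluster 8, which carries goblet and Paneth markers, held 14 of 47 distal and 19 of 268 proximal cells. Without it Itln1 (−0.86), Mmp7 (−0.36) and Ang4 (−2.67) were no longer higher distally and were not called in either direction. Genes of early endocrine progenitors were lower, with Neurog3, which starts endocrine fate, the Notch ligand Dll1, and Sox4, and so were the endocrine factors Foxa2 and Nkx2-2, the proximal factor Onecut2, Fabp1, Pgc, Top2a and Rab3c, while Cdc20, of the proliferation list with Top2a, was higher. The progenitor cluster 1, marked by Neurog3, held 64 of 268 proximal and 0 of 47 distal cells, and the progenitor list missed the threshold with an estimated correlation (adjusted p = 0.051). In medial cells Nts, Sct, Pla2g4c, Ang4, Clca1, Guca2a, Agr2, the sialyltransferase St3gal4 and the anion exchanger Slc26a4 were higher, and ghrelin (Ghrl) was lower. DESeq2 called 5 of these 10 genes, Nts, Sct, Guca2a, Agr2 and Ghrl.

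Distal cells had 238 genes higher and 173 lower of 8005 (DESeq2 149 in all), medial cells 9 higher and 1 lower (DESeq2 6 and 6). Nts had 0 counts in 1808670 proximal footprints, 1360 CPM in the distal plate and 6585 CPM in the medial plate, at least 820-fold and at least 3970-fold higher than the proximal group. These counts came from 3 of 47 distal cells, with 78.7% in 1 cell, and from 2 of 35 medial cells, with 70.5% in 1 cell. Pyy had a proximal median of 0 CPM (range 0 to 39.9), 1256 CPM distally and 136.5 medially. Pyy changed by 6.85 ± 0.50 distally in edgeR but was not called by DESeq2. Gcg reached 21036 CPM distally, above the proximal range of 4.83 to 14156. Sct stood at 380 (range 228 to 515), 1078 and 1935 CPM in proximal, distal and medial cells. Ghrl stood at 3119 (2462 to 7110), 1388 and 362 CPM, and Chgb, a granule protein, at 46436 (35527 to 72869), 23002 and 46359 CPM. Gip and Cck stayed inside the proximal range in both regions, and Insl5 had 0 counts everywhere. Agr2 rose by 2.47 ± 0.23 distally (edgeR adjusted p = 8.8e-06), and Neurog3 changed by −4.84 ± 0.58.

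In distal cells 5 of 6 distal genes were higher (5 adjusted over the list alone; median 7.38, or 5.84 with 3 absent genes at their bound, camera adjusted p = 3.6e-11), as were 5 of 9 goblet genes (5 adjusted over the list alone; 1.38, 4.4e-10) and 7 of 30 ribosomal protein genes (13 adjusted over the list alone; 0.92, 8.1e-12), which held with an estimated correlation. Paneth genes had 4 of 7 higher (4 adjusted over the list alone; 2.23, 1.7e-08, adjusted p = 0.051 with an estimated correlation), endoplasmic reticulum stress 7 of 17 higher (14 adjusted over the list alone; 0.80, 7.9e-13, adjusted p = 0.081 with an estimated correlation) and early progenitor genes 6 of 14 lower (9 adjusted over the list alone; −1.48, 3.3e-07, adjusted p = 0.051 with an estimated correlation). Endocrine factors (2 of 13 lower, 0.014) and mitochondrially encoded genes (1 of 7 lower, 0.040) passed with camera only, with adjusted p = 0.30 and 0.35 with an estimated correlation. Proximal genes (4 of 9 lower, 1 higher, camera adjusted p = 0.0734), secretory granule genes, enterocyte genes (median −0.36, mean 0.29), stem cell, proliferation and tuft genes did not pass. In medial cells the distal genes (1 of 6 higher, 4 adjusted over the list alone; median 3.53, or 2.97 with 2 absent genes at their bound, 1.3e-07), early progenitor genes (0 of 14, 5 lower adjusted over the list alone; 2.1e-04) and goblet genes (3 of 9 higher, 3 higher and 1 lower adjusted over the list alone; median 0.34, mean −0.13, 3.5e-05) passed with camera. With an estimated correlation they had adjusted p = 0.13, 0.19 and 0.19, and no medial list passed there. Tuft, endoplasmic reticulum stress, Paneth and proliferation lists also passed with camera alone in medial cells, and the Paneth list had a median of −0.11 while camera pointed up. Immune and stromal genes were too few for a list test. Each of both regions is a single plate, so region and plate cannot be told apart, and the p-values assume that it varies as the 5 proximal plates do. Without plate 2 the medial comparison called 21 genes, without plate 7 it called 17, and without the cells of the authors' cluster 8 the distal comparison called 225.

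**Figure D5:**
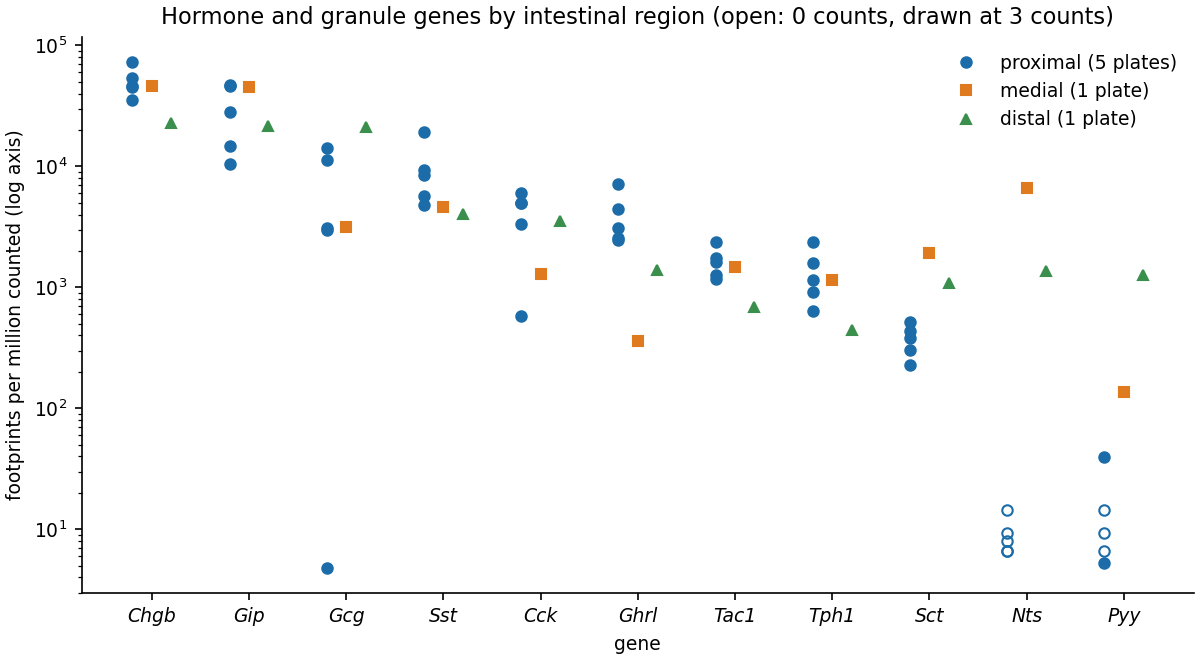
Footprints on hormone and granule genes in CPM (log axis) on 5 proximal plates, 1 medial plate and 1 distal plate, with open points for 0 counts drawn at 3 counts. Nts was absent from all proximal plates and stood at 6585 CPM medially and 1360 CPM distally.

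The Neurog3Chrono reporter follows time since Neurog3 was active, from green to red, and the tercile with the highest ratio of green to red (early) was compared with the lowest (late) within 7 plates. A cell can enter the early tercile through a dim red signal as well as a bright green one. Early cells had more footprints on the goblet genes Clca1, Guca2a, Spink4, Fcgbp and Tff3, the secretory regulators Spdef and Atoh1, the progenitor genes Dll1 and Sox4, the proliferation genes Mki67 and Top2a, the stem-linked Prom1 and Slc12a2, and Rplp0 and mt-Co1. Late cells had more on the hormones Sst, Ghrl, Gcg and Cck and on Tac1, on Tph1, which makes serotonin, on the hormone-processing Pcsk1, the ion channel Trpa1, the calcium sensor Scgn, the cofactor enzyme Gch1, the endocrine factors Isl1, Pax6 and Rfx6, on Vim and on Cdkn1a.

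Early cells had 366 genes higher and 417 lower of 2533 (DESeq2 313 and 413), and 508 of the 783 had the same direction on every plate. Clca1 was at least 3944-fold higher in early cells and Sst at least 4200-fold lower, both over the group. Ghrl changed by −6.86, Tph1 by −5.34 and Atoh1 by 5.98. Goblet genes had 6 of 6 higher (6 adjusted over the list alone; median 7.59, camera adjusted p = 1.7e-09) and secretory granule genes 10 of 13 lower (11 adjusted over the list alone; −2.86, 3.4e-07), which held with an estimated correlation. Early progenitor genes had 6 of 9 higher and 1 lower (6 and 1 adjusted over the list alone; 1.03, 0.0080, adjusted p = 0.25 with an estimated correlation), with −0.49 on the distal plate, which has 0 cells of cluster 1, and 0.77 to 1.67 on the others. Proliferation genes had 3 of 3 higher (3 adjusted over the list alone; 0.0080, adjusted p = 0.14 with an estimated correlation) and ribosomal protein genes 6 of 9 higher (6 adjusted over the list alone; 0.95, 0.0033, adjusted p = 0.11 with an estimated correlation). Endocrine factors had 5 of 10 lower (5 adjusted over the list alone; −0.94, 0.0046, adjusted p = 0.16 with an estimated correlation), proximal genes 3 of 4 lower (4 adjusted over the list alone; 0.011, adjusted p = 0.16 with an estimated correlation) and mitochondrially encoded genes 3 of 5 higher (5 adjusted over the list alone; 0.018, adjusted p = 0.26 with an estimated correlation). Stem cell, endoplasmic reticulum stress and enterocyte genes (median 0.062, mean −0.35) did not pass. The early tercile mixes cell kinds: without the cells of cluster 8 the comparison called 503 genes of 1859 tested, and only 2 goblet genes, both higher, could still be tested.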

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

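The comparison between batches was chosen after the MGI plates had been seen to hold mitotic and G0 cells, and the look at the pausing classes after the cell table had been read. Of 75 groups of plates, 8 had a plate standing apart from the others by Dixon's test, and chance does so in about 1 in 20 groups. No biological explanation was tested for them.

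Among the sorted RPE cells, G0 cells of MGI plate 8 had a median of 1135 genes per cell at equal depth, against 1095 to 1112 on the other plates. On MGI plate 7 the coding share of G0 footprints was 89.4%, against 89.9% to 90.2%. The mitochondrial share in mitotic cells was 0.481% on MGI plate 8, against 0.387% to 0.421%. Among proximal mouse plates, plate 8 had 1273 genes per cell at equal depth (others 1225 to 1238), and plate 7 had a coding share of 84.8% (others 86.8% to 87.5%). Pyy stood at 39.9 CPM on proximal plate 8, where the others had 0 to 5.31. All 18 of these footprints came from 1 of 56 cells. The median early minus late difference of the endocrine transcription factors was −1.04 on proximal plate 7, against −0.48 to −0.30. For the proliferation genes, of which 3 were measured, it was −0.89 on proximal plate 2, against 3.66 to 5.00.

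The difference between mitotic and interphase cells was not the same in both batches of RPE plates for 306 of 7218 genes (edgeR interaction, adjusted p below 0.05), larger in the MGI plates for 150 and smaller for 156. Among the genes with the largest such differences, GADD45A (1.92 higher in the MGI plates), the peptidase CPA4 (1.76 higher) and the calcium pump ATP2B4 (−1.24) were picked after their values were seen. Of 3204 genes called in both batches, 23 had opposite directions. For G0 cells the count was 431, with 222 larger and 209 smaller, and 49 of 1365 genes called in both batches had opposite directions. The secreted genes IGFBP3 (−2.71), TFPI2 (−2.47) and AMTN (−3.74) rose less or fell more in G0 cells of the MGI plates. The division genes MKI67, BUB1 and KIF20A, with 0 counts in G0 cells of the first plates, fell less in the MGI plates (interaction adjusted p = 2.8e-04, 0.015 and 0.044), so their near absence in G0 is a result of the first plates. These genes too were picked after their values were seen. The batches also differ in plate number, 8 against 7 and 2, and what else differed between them is not stated.

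The mouse cell table has a pair of classes that no comparison used. Of the mouse cells, 16 carried the authors' class cag_pausing, 14 of them proximal, 8 in cluster 1 and 11 in the early tercile of the reporter. The class gaa_pausing held 6 cells, all proximal, all in cluster 3 and none in the early tercile. How these classes were made is not stated, and 16 and 6 cells on 7 plates were too few for a test here.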

How the results depend on the processing

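Chosen only after the data were seen were the tests with a stricter minimum of footprints per cell, the MGI plates, the reporter batches alone, cluster 8 left out, each mitotic plate left out, and the codon tests. Of 8828 values of named genes under other settings, 8430 kept direction and side of the threshold (1048 of them under the minimum of 1000 footprints, which removed 0 cells and tests nothing), 315 lost the call, 70 gained it and 13 reversed. Over all genes and settings 103 calls reversed.

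Under DESeq2 the count of changed genes was 142, 193, 82 and 149 for arginine-free 3 h and 6 h and leucine-free 3 h and 6 h against rich medium (edgeR 348, 551, 167 and 413). It was 62 and 92 between the media at 3 h and 6 h (edgeR 117 and 183), 0 and 0 between times without arginine and without leucine (unadjusted p below 0.05: 134 and 102; edgeR 4 and 17), 1004 for G0 (2079) and 149 for distal cells (411). Without a low-count filter the counts were 34 and 38 between times, 41 for medial cells (10) and 1723 for the mouse reporter (783). Without it the median of all genes was −0.14 in the mitotic and medial comparisons (−0.0057 and −0.021 with it). Leaving out each plate gave 916 (without plate 11) to 1599 genes for G0 and 9 to 21 for medial cells (21 without plate 2, 17 without plate 7), 3714 to 3805 for mitotic cells and 347 to 486 for distal cells. A plate could not be left out of the starvation comparisons, where no residual degree of freedom would be left. The stricter minimum, which removes 135 mouse cells, gave 192, 3 and 502 for distal cells, medial cells and the mouse reporter. Narrower outer groups of that reporter gave 460. Leaving out cluster 8 gave 225 for distal cells and 503 for the reporter, with fewer genes tested. The KO, SR2 and first plates alone gave 1280, 456 and 1194 for geminin (2559) and 1523, 779 and 1241 for CDT1 (2536), from fewer plates.

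Without the replicate block of plates, arginine-free cells had 8 genes changed between times (4 with it), and no other count moved by over 1.5 times: 361, 574, 176 and 426 against rich medium, 121 and 194 between media, 24 between times without leucine, 4170 for mitotic cells, 2584 for G0, 2264 and 2271 for geminin and CDT1, and 800 for the mouse reporter. No paired analysis was possible because the mouse regions share no plate, and the lone medial and distal plates are taken to vary like proximal ones. Of 279 list tests 153 passed, 148 without the block, 128 with fry and 47 with an estimated correlation. With means over cells, mitotic cells had 20.4 more genes at equal depth, a call that medians over both batches did not give, and with medians 0.0334 points more mitochondrial footprints, which means did not give. Codon medians gave 2 codons at 3 h and 10 at 6 h without leucine, where means gave 10 and 20.

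Reversed values were in G0 with MGI plates instead SLC38A2 (−0.087), MVK (0.11) and LAMP2 (−0.064), and without plate 11 FARSB (0.010, against −1.47 without plate 12). For geminin they were SLC3A2 (−0.13), MARS1 (−0.012) and CALR (0.0055) in SR2 plates and CALR (0.0051) in KO plates, and for CDT1 SLC1A5 (0.018) and H2BC15 (0.015) in SR2 plates. Without cluster 8, distal Itln1 (−0.86), Mmp7 (−0.36) and Ang4 (−2.67) reversed, so their rise rests on those cells. For the other shifts the cause was not tested. In simulated counts, 19.4% of distal and 13.4% of medial 2-fold changes were found, with 1 plate per region, and 59.7% for the mouse reporter.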

Other observations

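Among the tests here, the S-phase, dim-red, spread between wells and cytosolic-footprint tests were chosen only after the result was seen.

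The reporters of the sorted RPE cells were read beside their populations. Median green and red signals were 621 and 11.2 in 724 mitotic cells, 17.1 and 864 in 2261 interphase cells, and 11.98 and 2773 in 291 G0 cells. Among mouse cells, the authors' cluster 1 had 68 of 72 cells in the early tercile and a median green signal of 219 against 20.0 over all cells. Cluster 8 had 36 cells, with 25 in the early tercile, a median green signal of 16.1 and a median red signal of 150.

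Histone and ribosomal protein genes were higher without arginine than without leucine at 6 h, by medians of 0.81 and 0.57, both short of the threshold with an estimated correlation (adjusted p = 0.082). Histone genes are rich in CGC and CGU, the codons that rose without arginine (a median of 6.92% of codons, 3.23% in ribosomal protein genes and 1.29% over all genes), so ribosomes held there could raise their counts. Other genes with as many of these codons differed by 0.056 (62 genes matched to histones, 95% interval −0.12 to 0.16) and −0.024 (2062 genes matched to ribosomal proteins, −0.047 to 0.0025), which argues against this as the whole cause for either group. At 3 h a part may come from it, since the difference rose with the share of these codons (0.030 per percent, 0.021 to 0.037) and genes matched to ribosomal proteins differed by 0.054 (0.041 to 0.071), while the slope at 6 h was 0.0033 (−0.0075 to 0.014). More cells in S phase stays open for the histones as a part of the cause. The DNA replication genes differed by 0.19 (0.058 to 0.24), where the geminin reporter's ratio of both lists would need 0.29. At 3 h they differed by 0.091 (0.022 to 0.147), where 0.284 would be needed. Both values fall short of the whole difference, but the ratio comes from RPE cells and may not carry over to HEK293T cells. All intervals given here come from resampling genes within a fit. They hold no spread between plates and do not show replication over plates. A direct effect of the missing amino acid was not tested.

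Goblet genes were higher in the early tercile of the mouse reporter. Footprints from other wells, spread over the plate, would reach early and late cells of a plate alike, and outside cluster 8, the likely source, the goblet share was at least 20.1 times as high in early cells on each proximal and medial plate, which argues against it there. Cells of cluster 8, with 73.8% of the goblet footprints of early cells, may add to the difference by entering the early tercile through a dim red signal, since 15 of these 25 cells had a green signal below the median of all cells. On the distal plate the ratio outside cluster 8 was 1.44, so there spread stays open and the difference lies in cluster 8. Of the 89 early cells outside cluster 8, 68 were in the progenitor cluster 1. Only 2 goblet genes could be tested without cluster 8, so a rise of the other goblet genes there is not shown. What raises goblet footprints in the other early cells of the proximal and medial plates stays open.

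Mitochondrially encoded genes were higher without arginine at 3 h, a call lost with an estimated correlation (adjusted p = 0.086). Fewer cytosolic footprints per cell are argued against by the lower plate's ratio to rich medium of 0.968. A few cells with very high shares are argued against by the median cell, whose mitochondrial share was 1.54 and 1.76 times that in rich medium on the plates. Without leucine the median cell's share was raised too, 1.76 and 1.25 times at 3 h and 1.64 and 1.43 times at 6 h. At 6 h without leucine, mean footprints per cell from other genes were 0.873 and 0.8145 times those in rich medium. Mitochondrial footprints per cell were 1.27 and 1.18 times, so part of that raised share goes with fewer other footprints. At 3 h without leucine, mitochondrial footprints per cell were 1.90 and 1.51 times. The rise is thus not confined to arginine-free medium. A response of mitochondrial translation to the medium stays a hypothesis that was not tested. A change in mitochondrial RNA or in how well mitochondrial ribosomes were recovered was not tested either.

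Chance as the source of the changed genes was tested by swapping populations within plates. For mitotic cells, 1 of 64 splits, the real one, gave as many as its 4002 genes, and the highest other gave 0 in edgeR. For the geminin and CDT1 reporters 1 of 30 splits did so, with 2559 and 2536 genes against 0 for the highest other. For the mouse reporter 1 of 64 did so, with 783 genes, and the highest other, with the terciles swapped on 1 plate, gave 182. Chance is unlikely as the whole cause for these 4 comparisons, but with 64 or 30 splits it is not excluded. The low counts of the other splits add nothing to this, since a swap turns a real difference into spread between plates. Both FUCCI reporters were tested with the same swaps. The comparisons with 1 or 2 plates per group allow no such test.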
